A study of Danio rerio with 56 samples.

How the data were processed

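Whole zebrafish were pooled, 25 per library, from 4 treatments at 5 ages, and polyadenylated RNA was sequenced as strand-marked libraries, per the labels' protocols. The submitters' processing notes name the genome build GRCz11 and the tools FastQC 0.11.8, MultiQC 0.9, HISAT2 2.0.5, SAMtools 1.5, Picard and HTSeq 0.9.1. The order of these steps, the annotation release and the counting options were not given in these sources. Counting by strand is therefore not known, and reads of overlapping genes, or of close copies such as the vitellogenins, globins and keratins, may be split among them. The authors deposited a table of raw read counts per Ensembl gene, with 32520 genes and 56 libraries. A second table holds a normalized signal, which the authors made by dividing counts by 1 factor per library, with DESeq2 per the table's name. In that deposited table, with 32266 genes, 100.0 percent of values in each column but one were whole multiples of the column's smallest value within 0.01. The exception, DMSO 64 d replicate 3, has a factor too close to 1 to check.

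The tables share 27913 genes, 4607 are in the raw table only and 4353 in the normalized table only. They do not hold the same counts, since raw reads per read recovered from the normalized table ranged from 1.09 to 2.37 between libraries, with a median of 1.5. The raw counts were the main values. In the raw table the column of EM+E2 2 d replicate 2 equals that of EM+E2 16 d replicate 3 in all 32520 genes. The first was left out as a copy, because the copied values correlate best with the recovered reads of the latter, and 55 libraries were used. Replicates carry the number in brackets in the titles, which differs from a second number there in EM at 8 and 16 d and EM+E2 at 64 d. In each library 20791 to 24882 genes had a read. Mitochondrially encoded genes took 3.97 to 20.4 percent of the reads, with a median of 8.12 percent.

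Symbols came from the supplied table of gene names by Ensembl identifier, and 29201 genes of the raw table had one. Of 601 listed symbols 549 were matched, some through a name without the copy's letter, so that cyp19a1a and cyp19a1b fell on 1 gene, CYP19A1. A supplied gene table, of the assembly GRCz12tu, was used only for which genes neighbour each other.

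Counts were tested with edgeR 4.0.16 in R 4.3.3. Each age had 1 fit of group means over its 4 treatments, and the DMSO libraries of all ages had another. Genes were kept by filterByExpr at a minimum count of 10 and a minimum total of 15, libraries were scaled by TMM, and contrasts were tested with edgeR's quasi-likelihood F test. The adjusted p of a gene is from that test with Benjamini-Hochberg adjustment over all genes of the contrast, and a gene passed at an adjusted p under 0.05. The contrasts were each treatment against DMSO, EM+E2 against EM, the interaction (EM+E2 less EM less E2 plus DMSO) and successive ages in DMSO. EM+E2 against E2 was fitted only for the correlations of EM effects, with 4 genes lower at 2 d and 0 calls at 8, 16, 32 and 64 d (1994, 1028, 2321 and 1952 at an unadjusted p under 0.05). Where a group had no read, a bound on the fold was set against 3 counts over the group, and with 1 to 3 reads a ratio was given with a 95% exact counting interval.

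Named genes followed a rule. Part 1 is a panel, vtg1, esr1, cyp19a1b, cyp19a1a, foxl2a, amh, dmrt1, gsdf, ddx4, zp3b and cyp11c1, in each treatment comparison where measured. Part 2 is, per comparison of 2 groups, up to 5 genes higher and 5 lower with the largest log2 fold change among those past the test with a change of 1 or more, a mean of 1 CPM or more in the higher group, groups fully apart and a symbol other than a clone or placeholder name. For the interaction the condition on groups was left out. Part 3 is, per list, up to 4 members past the test with the smallest adjusted p, or up to 2 with the smallest p where none passed, and fewer were named where space required, as were list tests. Some genes that the rule takes in are not reported here.

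For 30 gene lists camera (limma 3.58.1) was run with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over all 745 tests of a list in a treatment comparison. The lists were cytosolic ribosomal protein, vitellogenin, other oestrogen-responsive, oocyte, ovarian somatic, testis somatic, steroidogenic, germ cell, meiosis, sperm and spermatid, pituitary and reproductive neuroendocrine, brain, cholesterol synthesis, fatty acid synthesis, liver, exocrine pancreas, intestine, fast muscle, lens and retina, globin, skin and keratin, cartilage and bone, cell cycle, unfolded protein response, heat shock and oxidative stress, glucocorticoid-responsive, xenobiotic metabolism, innate immune, circadian and mitochondrially encoded genes. Members past the gene test were counted over all genes and adjusted over the list alone. The estimated p comes from camera with a correlation estimated per list. The function fry was run too; its directional p tests whether a list's genes move, on balance, one way, and its mixed p whether they change in either direction.

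The comparisons, tests, lists, naming rule and these alternatives were set before the data were examined: DESeq2 1.42.0, RLE scaling, no filter on counts, all ages in 1 fit, the replicate number as a block, leaving out each library, estimated correlation, fry, and for correlations genes at a mean of 10 CPM or more and log2 CPM means with a prior count of 5. Chosen after seeing the data were recovered reads in place of raw counts, leaving out 5 libraries nearest by rank correlation (over genes at a mean count of 20 or more) to a library of another age, a block for runs of 12 library numbers, which lie within treatments, and keeping the copied column. Replicate numbers pair EM with EM+E2 at 16 d, by the data alone: deviations of same-numbered libraries correlated at 0.369, 0.119 and 0.264, although EM replicate 2 did so more with EM+E2 replicate 3 (0.155). With a library left out of a group of 2, the lone library is taken to vary like the other groups of the fit.

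The scripts were tested on simulated counts drawn from the real genes' means and library sizes, with 100 genes changed 4-fold and 100 changed 16-fold. For EM against DMSO edgeR called 57 and 97 of them at 8 d (13 unchanged genes called, 19955 genes run), 25 and 82 at 32 d (5, 20784) and 38 and 95 at 64 d (10, 20907). For EM+E2 against EM at 64 d it called 32 and 82 (7, 20955), and for DMSO at 64 against 32 d 22 and 68 (3, 21691). DESeq2 called 78 and 98 (41), 52 and 97 (40), 67 and 100 (52), 57 and 92 (41) and 48 and 92 (50) of the same.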

Results

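The series sampled whole zebrafish of the AB strain at 5 ages, 2, 8, 16, 32 and 64 d, and each library holds polyadenylated RNA from a pool of 25 fish whose sex the labels do not give. Fish were kept in the solvent DMSO, in exemestane (EM) at 10 µg/L, in 17β-estradiol (E2) at 100 ng/L, or in both (EM+E2). Exemestane is a steroidal inhibitor of aromatase, the enzyme that makes oestrogens from androgens. Of 56 libraries in 20 groups, 55 were used. Groups held 3 libraries, except for 2 in DMSO and EM+E2 at 2 d and 2 in EM, E2 and EM+E2 at 64 d. Libraries held 4039030.0 to 10144213 counted reads, with a median of 9107346. Levels are given as mean ± SD in counts-per-million units (CPM), which for a whole-body pool are shares of the RNA of all organs together. The labels do not say whether the pools of a group were raised apart, so the p-values measure only the spread between libraries. Counting intervals and lower bounds on folds cover counting error only. For gene lists the adjusted p is that of a test with a preset correlation between genes, and the estimated p that with a correlation estimated from these libraries, adjusted likewise. Of 244 list calls with the preset value only those of the oocyte genes at 32 d, in EM and in EM+E2 against DMSO, held with the estimated one.

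Development in the solvent controls was followed from each age to the next. Between 2 and 8 d (n = 2 and 3) digestive genes rose: 18 of 22 exocrine pancreas enzymes rose and 1 fell, and 13 of 19 intestine genes rose. The trypsin gene prss59.2 rose from 1.55 ± 0.791 to 980.1 ± 272 CPM (log2 fold change 9.32, adjusted p 0.00147). MEP1B, an intestinal protease gene, had no read at 2 d and was at least 139-fold higher at 8 d (adjusted p 2.44e-05). Division genes went the other way, with 24 of 25 cell cycle genes lower, and the proliferation marker mki67 fell from 815 ± 79.5 to 15.1 ± 2.89 CPM (adjusted p 4.95e-06). Of 26 lens and retina genes 14 rose. Of 28 circadian genes 18 rose and 1 fell, with the clock repressor gene NR1D1 rising from 2.13 ± 0.718 to 351 ± 46.9 CPM. The embryonic globin gene hbbe3 had no read at 8 d and was at least 137-fold lower. In all, 2308 genes rose and 2429 fell of 22148 tested. When adjusted over the list alone, 19 pancreas enzymes, 13 intestine, 16 lens and retina and 23 circadian genes rose, and 24 cell cycle genes fell. The changed genes numbered 2358 without DMSO 2 d replicate 1 and 3150 without DMSO 8 d replicate 2.

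Between 8 and 16 d (n = 3 and 3) division and sterol genes rose: 21 of 25 cell cycle genes, mki67 going from 15.1 ± 2.89 to 149 ± 31.1 CPM (log2 fold change 3.30, adjusted p 0.000775), and 9 of 24 cholesterol synthesis genes. Of 18 unfolded protein response genes 7 rose. The antiviral gene RSAD2 rose from 0.428 ± 0.488 to 27.6 ± 15.3 CPM, while hamp, the gene of the iron hormone hepcidin, fell from 28.7 ± 5.79 to 0.540 ± 0.460 CPM. Of 31 innate immune genes 8 rose and 1 fell. The muscle breakdown gene FBXO32 fell from 186 ± 39.8 to 4.00 ± 2.53 CPM (log2 fold change -5.53, adjusted p 0.00145). In all, 818 genes rose and 205 fell, and DESeq2 called 2034. If adjusted over the list alone, 23 cell cycle, 11 cholesterol synthesis, 15 unfolded protein response and 9 innate immune genes rose. The changed genes numbered 583 and 507 without DMSO 16 d replicates 1 and 2, and 338, 260 and 375 without DMSO 8 d replicates 1, 2 and 3.

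Between 16 and 32 d (n = 3 and 3) genes of egg cells rose: 19 of 27 oocyte genes (median 6.65, or 5.25 with members lacking reads at their bound) and 10 of 18 germ cell genes. The egg envelope gene zp3b (ENSDARG00000039828) rose from 1.07 ± 0.939 to 39.9 ± 21.9 CPM (log2 fold change 5.25, SE 0.86, adjusted p 0.00551). The oocyte linker histone gene h1m rose from 0.350 ± 0.222 to 53.1 ± 40.6 CPM (log2 fold change 7.25, adjusted p 0.000877) and the germ cell helicase gene DDX4 (ENSDARG00000014373) from 3.34 ± 0.957 to 18.3 ± 11.7 CPM (log2 fold change 2.46, adjusted p 0.0161). The adult globin gene hbaa1 rose from 0.802 ± 0.761 to 941 ± 281 CPM while the embryonic globin gene hbae3 fell from 172 ± 39.6 to 0.267 ± 0.462 CPM, among 2 of 8 globins higher and 3 lower. Of 20 cartilage and bone genes 4 rose and 1 fell. The myosin gene myha rose from 9.26 ± 2.88 to 27218 ± 23663 CPM. The yolk precursor gene vtg1 (ENSDARG00000092233) did not pass, at 100.3 ± 174 against 2.24 ± 3.89 CPM (adjusted p 0.36). In all, 372 genes rose and 70 fell, and DESeq2 called 1007. With p adjusted over the list alone, 25 oocyte, 14 germ cell, 10 cartilage and bone genes, 3 globins, 7 of 8 vitellogenins (median 5.90) and 4 of 9 other oestrogen targets rose. The vitellogenins summed to 773 CPM in DMSO 32 d replicate 1 but 2.32 and 1.66 in replicates 2 and 3, and without replicate 1 vtg1 was at -4.72. The changed genes numbered 177 and 180 without DMSO 16 d replicates 1 and 2, and 242 without DMSO 32 d replicate 1. DDX4 did not pass without any of these 3 libraries (log2 fold changes 2.3, 2.37 and 1.90) or with all treatments in 1 fit (2.46).

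Between 32 and 64 d (n = 3 and 3) 22 of 27 oocyte, 17 of 18 germ cell and 19 of 25 cell cycle genes rose. The egg envelope gene zp3b rose from 39.9 ± 21.9 to 1028 ± 627 CPM (log2 fold change 4.68, SE 0.80, adjusted p 0.00175). The cyclin gene CCNB1 rose from 25.2 ± 15.1 to 602 ± 255 CPM (log2 fold change 4.57, adjusted p 0.000249). DDX4 rose from 18.3 ± 11.7 to 116 ± 27.7 CPM. Of 14 steroidogenic genes 4 rose. Nerve, eye and muscle genes fell, in 17 of 19 brain, 12 of 26 lens and retina and 9 of 23 fast muscle genes. The neuronal gene ELAVL3 fell from 161 ± 4.81 to 24.5 ± 12.3 CPM and the fast myosin gene myhz2 from 12497 ± 10256 to 249 ± 8.08 CPM. The level of vtg1 was 3276 ± 3673 against 100.3 ± 174 CPM and did not pass (adjusted p 0.124), although it did with all treatments in 1 fit (log2 fold change 4.99) and without DMSO 32 d replicate 1, which held nearly all of the 32 d reads. Here 2307 genes rose and 2390 fell, 2171 in all without DMSO 64 d replicate 1. Adjusted over the list alone, 25 oocyte, 18 germ cell, 21 cell cycle and 4 steroidogenic genes rose, and 17 brain, 19 lens and retina and 14 fast muscle genes fell.

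**Figure D1:**
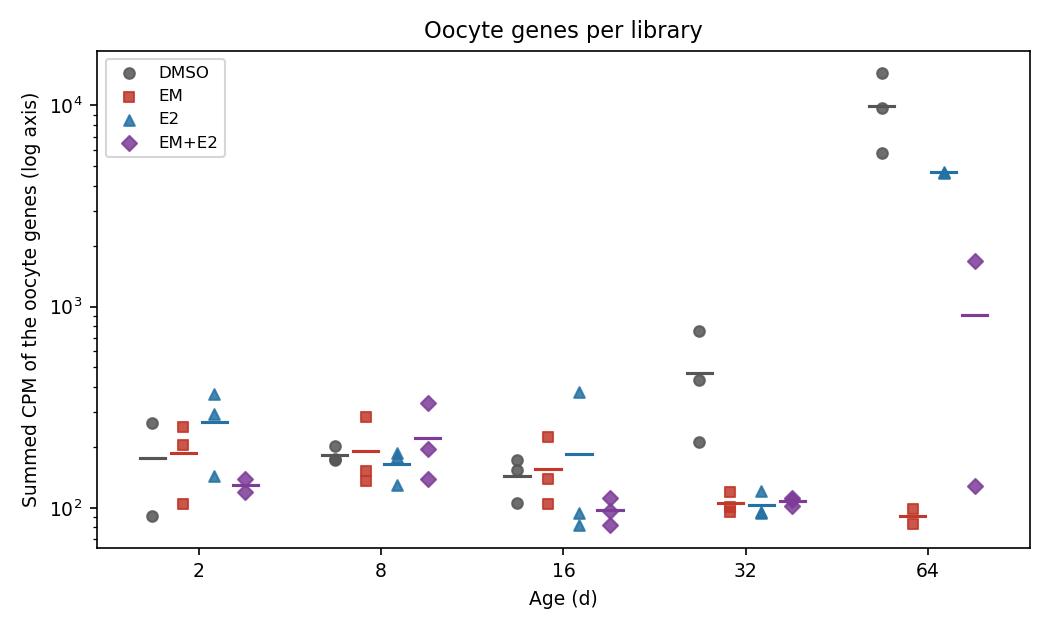
Summed level of the oocyte genes (unscaled CPM, log axis) in each library against age, by treatment, with a dash at each group's mean. The 2 EM libraries at 64 d held 83.1 and 99.1.

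At 64 d, EM was compared with DMSO (n = 2 and 3) to ask what inhibiting aromatase does to the fish. All 27 measured oocyte genes fell, with a median log2 fold change of -9.44, or -8.38 with the 3 members lacking reads at their bound (list test adjusted p 1.65e-22, estimated p 0.83). The egg envelope gene zp3b fell from 1074 ± 679 to 0.916 ± 0.299 CPM (log2 fold change -10.18, SE 1.72, adjusted p 0.00325). The oocyte growth factor gene bmp15 fell from 85.7 ± 27.0 to 0.306 ± 0.148 CPM (log2 fold change -8.07, SE 0.92, adjusted p 0.00217). No read of zp2.1 was found in EM, at least 669-fold lower than 102 ± 57.0 CPM (adjusted p 0.0041). Of 8 vitellogenins, the yolk precursors that oestrogen switches on in the liver, 7 fell (median -8.62, list test adjusted p 4.88e-05, estimated p 0.857). The level of vtg1 fell from 3415 ± 3915 to 4.67 ± 0.348 CPM (log2 fold change -9.51, SE 1.45, adjusted p 0.00244). The gene vtg6 had no read, at least 1343-fold lower (adjusted p 0.00699). Other oestrogen targets fell in 3 of 8 cases, F13A1 (ENSDARG00000045453), a clotting factor gene, from 97.6 ± 119 to 0.605 ± 0.710 CPM (log2 fold change -7.30, adjusted p 0.00421). That list did not pass (adjusted p 0.0913, estimated p 0.895), but did without DMSO replicate 1 or 3 (0.0248 and 0.0368). When adjusted over the list alone, 27 oocyte genes, 7 vitellogenins and 5 other oestrogen targets fell. The call of vtg6 ended without EM replicate 1 or 2.

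Germ cell and division genes were lower too. Of 18 germ cell genes 14 fell (list test adjusted p 1.56e-07, estimated p 0.857). DND1, which protects germ cell RNA, fell from 43.1 ± 16.7 to 0.960 ± 0.777 CPM (log2 fold change -5.47, SE 0.87, adjusted p 0.00262). DDX4 was at 41.7 ± 7.57 against 119.8 ± 30.9 CPM and did not pass (log2 fold change -1.52, adjusted p 0.0555), although it did with DESeq2, RLE scaling and no filter. Of 25 cell cycle genes 18 fell and 2 rose (adjusted p 3.08e-09, estimated p 0.857). The mitotic kinase gene AURKB fell from 112 ± 54.1 to 8.35 ± 3.27 CPM (log2 fold change -3.74, SE 0.53, adjusted p 0.00227). Of 18 unfolded protein response genes 9 fell and 1 rose (adjusted p 0.00381, estimated p 0.857). HSPA5, the main chaperone of the endoplasmic reticulum, fell from 1544 ± 462 to 178 ± 28.7 CPM (log2 fold change -3.12, SE 0.47, adjusted p 0.00243). The steroidogenic genes split, 4 of 16 lower and 2 higher, with a median of 0.50, a mean of -0.86 and a test on the lower side (adjusted p 0.962). CYP11A1, which starts steroid synthesis, fell from 57.1 ± 38.6 to 0.563 ± 0.654 CPM (log2 fold change -6.64, adjusted p 0.0098), and CYP17A1, an enzyme of androgen synthesis, fell from 104 ± 71.0 to 6.18 ± 2.94 CPM (log2 fold change -4.06, adjusted p 0.0172). If adjusted over the list alone, 17 germ cell, 20 cell cycle, 9 unfolded protein response and 4 steroidogenic genes fell, and 5 steroidogenic genes rose. The calls of CYP11A1 and CYP17A1 ended without EM replicate 1 (log2 fold changes -8.97 and -3.65) and without EM replicate 2 (-5.78 and -4.65).

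Testis somatic genes were higher: 8 of 11 rose and 0 fell (median 1.77, list test adjusted p 0.000263, estimated p 0.529). The Sertoli cell hormone gene amh (ENSDARG00000014357) rose from 0.654 ± 0.403 to 13.8 ± 4.2 CPM (log2 fold change 4.39, SE 0.61, adjusted p 0.00223). The Leydig cell hormone gene insl3 rose from 0.368 ± 0.638 to 18.1 ± 19.2 CPM (log2 fold change 5.65, SE 1.28, adjusted p 0.0119), and the retinoic acid enzyme gene CYP26B1 from 15.5 ± 5.67 to 67.5 ± 8.82 CPM (log2 fold change 2.12, SE 0.35, adjusted p 0.00287). The male pathway gene DMRT1 (ENSDARG00000007349) rose from 0.993 ± 0.416 to 4.87 ± 0.942 CPM (log2 fold change 2.29, SE 0.60, adjusted p 0.0193), and the gonadal growth factor gene gsdf (ENSDARG00000075301) from 4.72 ± 2.35 to 15.7 ± 1.16 CPM (log2 fold change 1.73, SE 0.50, adjusted p 0.028). Of 14 meiosis genes 1 rose, SYCP3 of the synaptonemal complex, from 3.04 ± 2.15 to 12.5 ± 4.07 CPM (adjusted p 0.047), and 2 fell. The list did not pass (adjusted p 0.589). Of 18 sperm and spermatid genes 1 fell (list adjusted p 0.659). Of 7 ovarian somatic genes 1 fell, and that list's median (0.64) and mean (-0.20) differ in sign, with the test on the higher side (adjusted p 0.858). The ovarian transcription factor gene FOXL2 (ENSDARG00000068417) was at 0.456 ± 0.210 against 1.2 ± 0.741 CPM and did not pass (adjusted p 0.273). The oestrogen receptor gene ESR1 (ENSDARG00000004111) was at 0.708 ± 0.422 against 9.51 ± 12.7 CPM and did not pass (adjusted p 0.0553), but did with DESeq2, RLE scaling, no filter, recovered reads (-3.17) and without DMSO replicate 1 or 2 (log2 fold changes -4.28 and -4.18). The androgen synthesis gene cyp11c1 (ENSDARG00000042014) was at 1.88 ± 0.0963 against 0.456 ± 0.149 CPM (adjusted p 0.0555) and passed without DMSO replicate 2 (2.28). Aromatase was looked up only as CYP19A1, too low to test at any age. With p adjusted over the list alone, 10 testis somatic genes rose, 0 meiosis genes rose or fell, and 1 sperm and 1 ovarian somatic gene fell. Without EM replicate 1 the calls of DMRT1, gsdf and SYCP3 ended (log2 fold changes 2.48, 1.81 and 2.35), and without EM replicate 2 those and that of insl3 did (2.08, 1.66, 1.67 and 3.63). DMRT1 and SYCP3 did not pass without DMSO replicate 1 (2.09 and 1.58), nor SYCP3 without DMSO replicate 3 (2.00). With all ages in 1 fit DMRT1, gsdf and SYCP3 did not pass (2.5, 1.96 and 2.24). Nor did SYCP3 with RLE scaling (1.91) or the library-number block (1.98), gsdf with that block (1.73), insl3 with DESeq2 (5.49) and DMRT1 with recovered reads (1.61) or the replicate block (2.12).

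Pancreas, skeletal and brain genes were higher in EM at 64 d. Of 22 exocrine pancreas enzymes 16 rose and 1 fell (median 1.5, list test adjusted p 3.59e-06, estimated p 0.678). The carboxypeptidase gene CPA1 rose from 127 ± 28.1 to 627 ± 153 CPM (log2 fold change 2.3, SE 0.33, adjusted p 0.00229). Of 20 cartilage and bone genes 9 rose and 1 fell (adjusted p 0.00195, estimated p 0.857). The cartilage collagen gene COL10A1 rose from 632 ± 114 to 1626 ± 225 CPM (log2 fold change 1.36, adjusted p 0.00703). Of 19 brain genes 8 rose and 0 fell (adjusted p 0.00546, estimated p 0.857), with the glial filament gene GFAP rising from 6.18 ± 4.24 to 28.7 ± 1.45 CPM (log2 fold change 2.2, adjusted p 0.0111). Xenobiotic metabolism genes rose in 6 of 15 cases (adjusted p 0.0217, estimated p 0.857), cyp1c1 from 5.28 ± 2.70 to 29.1 ± 11.3 CPM. Adjusted over the list alone, 18 pancreas enzymes, 13 cartilage and bone, 10 brain and 6 xenobiotic metabolism genes rose, and 1 pancreas enzyme, 1 cartilage and bone gene and 1 brain gene fell. Without EM replicate 1 the calls of COL10A1 and GFAP ended (log2 fold changes 1.22 and 2.15), as did that of GFAP without EM replicate 2 (2.26). With all ages in 1 fit CPA1 and COL10A1 did not pass (2.56 and 1.61). The xenobiotic list did not without DMSO or EM replicate 1 (adjusted p 0.0521 and 0.0502).

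These other lists did not pass at 64 d. Circadian genes split, 4 of 28 higher and 5 lower (list adjusted p 0.616). Of 24 cholesterol synthesis genes 2 rose and 3 fell, led by NSDHL, from 86.0 ± 14.8 to 16.2 ± 2.45 CPM (0.577). Of 21 heat shock and oxidative stress genes 3 rose and 4 fell, with a median of -0.07, a mean of 0.04 and a test on the lower side (0.751), and of 30 innate immune genes 4 rose and 2 fell (0.432). Rises were found in 4 of 19 skin and keratin genes (0.0856), 2 of 14 fatty acid synthesis (0.481), 2 of 19 intestine (0.232), 1 of 26 liver (0.308), 1 of 13 glucocorticoid-responsive (0.201) and 1 of 23 fast muscle genes (0.121). None passed among 28 cytosolic ribosomal protein genes (list adjusted p 0.85), 4 globins (0.712), 12 mitochondrially encoded genes (0.974) and 6 pituitary and reproductive neuroendocrine genes (0.985). The last had a median of -0.61, a mean of -0.43 and a test on the higher side. When adjusted over the list alone, those higher and lower were 5 and 5 circadian, 4 and 4 heat shock, 2 and 2 innate immune and 2 and 2 cholesterol synthesis genes. Likewise higher were 4 skin, 2 fatty acid, 1 liver, 1 glucocorticoid-responsive, 2 intestine and 0 fast muscle genes. NSDHL did not pass with all ages in 1 fit (-2.15). Each without 1 library, these lists passed: skin (adjusted p 0.0115 and 0.0301 without DMSO or EM replicate 2), fast muscle (0.0159, EM 2), liver (0.0316, DMSO 2), intestine (0.041, DMSO 2) and glucocorticoid-responsive genes (0.0369, EM 1).

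Of 21383 genes tested at 64 d, 2903 rose and 3762 fell in EM. RLE scaling, with 2144 higher and 4172 lower, moved the median of all genes by -0.15 on the log2 scale against TMM here, by -0.13 in EM+E2 and by -0.12 in E2, and the falls above are far beyond that. The changed genes numbered 2031 without EM replicate 1 and 2243 without EM replicate 2.

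**Figure D2:**
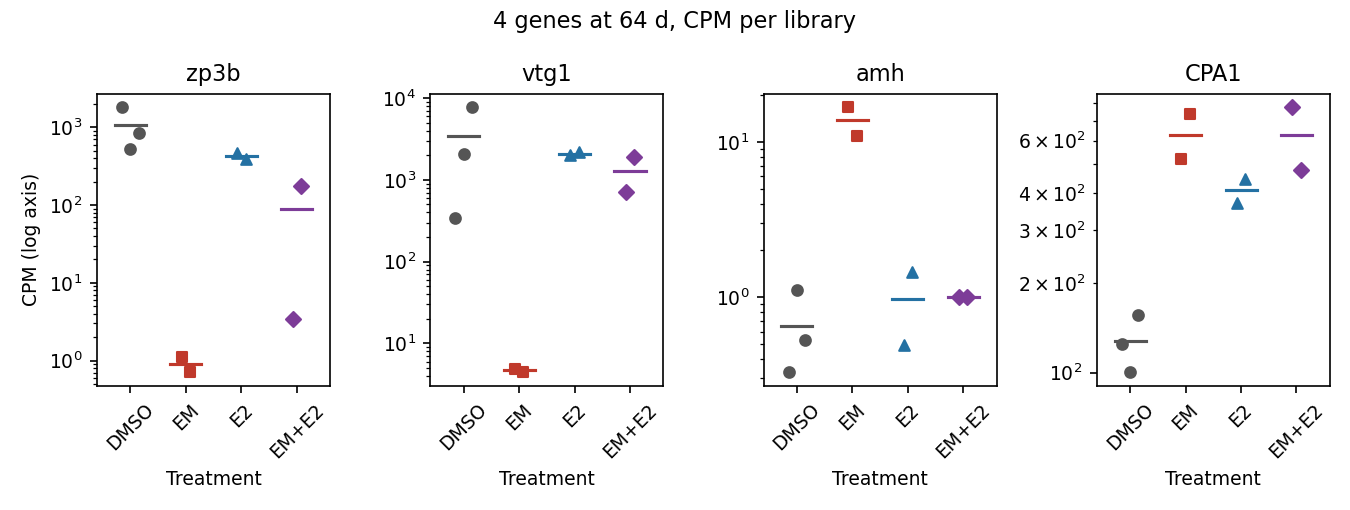
Level of zp3b, vtg1, amh and CPA1 (TMM-scaled CPM, log axis) in each library at 64 d by treatment, with a dash at each group's mean. The mean of zp3b was 1074 ± 679 in DMSO and 0.916 ± 0.299 in EM (± SD).

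With E2 added to EM, the 64 d fish were again compared with DMSO (n = 2 and 3). Egg genes were still low: 20 of 27 oocyte genes fell (median -3.59, list test adjusted p 1.65e-11, estimated p 0.857), as did 17 of 18 germ cell genes (adjusted p 9.87e-11, estimated p 0.857) and 21 of 25 cell cycle genes (adjusted p 6.45e-11, estimated p 0.857). The growth factor genes bmp15 and GDF9 fell from 85.7 ± 27.0 to 2.57 ± 3.01 CPM (log2 fold change -5.05, SE 0.74, adjusted p 0.00416) and from 40.3 ± 21.5 to 2.07 ± 2.29 CPM (log2 fold change -4.28, adjusted p 0.00554). DDX4 fell from 119.8 ± 30.9 to 16.0 ± 14.6 CPM (log2 fold change -2.90, SE 0.58, adjusted p 0.0074). DND1 fell from 43.1 ± 16.7 to 2.35 ± 2.69 CPM. The mitotic gene cdca9 fell from 54.7 ± 5.23 to 0.279 ± 0.238 CPM. The egg envelope gene zp3b was at 3.45 and 174.6 CPM in the 2 libraries (log2 fold change -3.59, adjusted p 0.0503) and passed with DESeq2, RLE scaling, no filter, all ages in 1 fit (-3.38), recovered reads (-3.28), the library-number block (-5.06) and without DMSO replicate 2 (-3.92) or EM+E2 replicate 2 (-8.27), but not with the replicate block or without DMSO replicate 1 or 3 or EM+E2 replicate 1 (-2.62 without the last). None of the 8 vitellogenins passed (median -1.95, list adjusted p 0.442, or 0.0137 without DMSO replicate 1), with vtg1 at 1296 ± 825 against 3415 ± 3915 CPM (adjusted p 0.288). Of 11 testis somatic genes 4 rose (list adjusted p 0.157), CYP26B1 from 15.5 ± 5.67 to 69.3 ± 14.2 CPM, whereas amh (0.63, adjusted p 0.491), DMRT1 (-0.96, 0.325) and gsdf (-0.15, 0.846) did not pass. Of 14 meiosis genes 5 fell (adjusted p 0.0213, estimated p 0.857). Pancreas enzymes rose in 16 of 22 cases (adjusted p 6.43e-06, estimated p 0.722), with CPA1 going from 127 ± 28.1 to 628 ± 213 CPM. Brain genes rose in 10 of 19 (adjusted p 0.00381, estimated p 0.857), GFAP from 6.18 ± 4.24 to 44.1 ± 2.22 CPM, and xenobiotic metabolism genes in 6 of 15 (adjusted p 0.0393, estimated p 0.857). Of 18 unfolded protein response genes 8 fell and 1 rose (adjusted p 0.00356, estimated p 0.857), HSPA5 falling from 1544 ± 462 to 257 ± 152 CPM. CYP17A1 fell from 104 ± 71.0 to 4.86 ± 6.56 CPM. ESR1 (-2.28, adjusted p 0.163) and FOXL2 (-0.96, 0.435) did not pass, nor did cyp11c1 on 3 reads (ratio 0.373, 95% counting interval 0.0675 to 1.38, adjusted p 0.28). In all, 2899 genes rose and 3624 fell. If adjusted over the list alone, 24 oocyte, 18 germ cell, 22 cell cycle, 5 meiosis and 10 unfolded protein response genes fell, and 17 pancreas, 12 brain, 6 xenobiotic, 4 testis somatic and 1 unfolded protein response genes rose. The changed genes numbered 812 and 3466 without EM+E2 replicates 1 and 2, and 4314 without DMSO replicate 1. HSPA5 did not pass without EM+E2 replicate 1 (log2 fold change -2.08), nor the meiosis list without it or DMSO replicate 2 (adjusted p 0.162 and 0.12), nor the xenobiotic list without DMSO replicate 1 or EM+E2 replicate 1 or 2 (0.0874, 0.0934 and 0.0805), nor CPA1 with all ages in 1 fit (2.56). Without EM+E2 replicates 1 and 2 the log2 fold changes were -2.18 and -4.39 for DDX4, -4.18 and -7.54 for bmp15, -3.44 and -6.46 for GDF9 and -3.44 and -8.78 for CYP17A1, each still past the test.

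E2 alone against DMSO at 64 d (n = 2 and 3) gave 1 call, the unnamed gene ENSDARG00000117707. It rose from 4.54 ± 0.557 to 29.6 ± 0.421 CPM (log2 fold change 2.70, SE 0.24, adjusted p 0.0121). It was at 22.3 in EM and 49.8 in EM+E2, and was chosen outside the naming rule after its values were seen. By list test, pancreas enzymes were higher (median 0.96, adjusted p 4.23e-05, estimated p 0.751), as were brain (adjusted p 0.00879, estimated p 0.857) and cartilage and bone genes (adjusted p 0.00333, estimated p 0.857). Oocyte (median -1.24, adjusted p 0.000846, estimated p 0.903), germ cell (adjusted p 0.000403, estimated p 0.86) and cell cycle genes (adjusted p 4.02e-06, estimated p 0.857) were lower, while vitellogenins (0.594) and testis somatic genes (0.115) did not pass. Short of the test were CPA1 at 408 ± 54.5 against 127 ± 28.1 CPM (adjusted p 0.0728), GFAP at 32.6 ± 3.63 against 6.18 ± 4.24 CPM (0.0797) and bmp15 at 28.2 ± 3.48 against 85.7 ± 27.0 CPM (0.129). The log2 fold changes of zp3b, vtg1, ESR1, DDX4, amh, gsdf, DMRT1 and FOXL2 were -1.34, -0.71, -0.97, -0.97, 0.59, 0.29, -1.14 and -0.62, the smallest adjusted p among them being 0.247. With p adjusted over the list alone, 8 pancreas enzymes, 4 cartilage and bone, 3 testis somatic and 2 brain genes rose and 2 cell cycle genes fell, with no oocyte gene, germ cell gene or vitellogenin. The single call of edgeR stood beside 5992 genes at an unadjusted p under 0.05 and 2437 calls by DESeq2. It became 0 without DMSO replicate 1 or either E2 library, 10 without DMSO replicate 2 and 2493 without DMSO replicate 3, when CPA1 (1.86) and GFAP (2.94) passed. These 2 genes also passed with DESeq2, as did bmp15, with recovered reads (415 calls) and with the replicate block (1211), and GFAP with all ages in 1 fit. Brain genes as a list did not pass without E2 replicate 1 (adjusted p 0.268), and vitellogenins did without DMSO replicate 1 (0.00638). The gene called did not pass with all ages in 1 fit (2.79) or the library-number block (2.67).

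EM+E2 against EM at 64 d (n = 2 and 2) asked what E2 adds to the inhibitor. Yolk and egg genes were higher as lists: vitellogenins with a median of 6.53, or 6.48 at bounds (adjusted p 4.5e-34, estimated p 0.355), oocyte genes with 5.74, or 5.20 (adjusted p 4.91e-47, estimated p 0.562), and other oestrogen targets with 0.94 (adjusted p 1.14e-06, estimated p 0.804). Levels of vtg1 were 1296 ± 825 against 4.67 ± 0.348 CPM (log2 fold change 8.11, SE 1.38, adjusted p 0.371). Those of F13A1 were 100.0 ± 49.6 against 0.605 ± 0.710 CPM (log2 fold change 7.33, adjusted p 0.371). The level of zp3b was 89.0 ± 121 against 0.916 ± 0.299 CPM (log2 fold change 6.58, adjusted p 0.418). Testis somatic (adjusted p 2.59e-08, estimated p 0.275), meiosis (adjusted p 2.74e-18, estimated p 0.275) and sperm genes (adjusted p 8.6e-15, estimated p 0.45) were lower by list test. Here amh was at 1.00 ± 0.00327 against 13.8 ± 4.2 CPM (log2 fold change -3.77, adjusted p 0.371) and DMRT1 at 0.502 ± 0.0773 against 4.87 ± 0.942 CPM (log2 fold change -3.24, adjusted p 0.399). Further values were gsdf at log2 -1.88 (adjusted p 0.753), DDX4 at -1.38 (1), ESR1 at 1.44 (1) and cyp11c1 on 3 reads in EM+E2 (ratio 0.0891, 95% counting interval 0.0176 to 0.281, adjusted p 0.576). Adjusted over the list alone, 24 oocyte genes, 7 vitellogenins and 3 other oestrogen targets rose, and 6 meiosis and 4 testis somatic genes fell. Over all genes edgeR called 0, beside 761 at an unadjusted p under 0.05 and 158 calls by DESeq2, which included vtg1, F13A1, zp3b, amh and DMRT1. The count was 177 without EM+E2 replicate 1, when vtg1 and zp3b passed, and 1 without EM replicate 1. Without EM+E2 replicate 2 the log2 fold change of zp3b was 1.9.

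The interaction at 64 d, whether the response to E2 differed between fish with and without EM, also had 0 calls by edgeR, with 3108 genes at an unadjusted p under 0.05 and 365 calls by DESeq2. As lists, oocyte genes (adjusted p 9.22e-27, estimated p 0.803) and vitellogenins (adjusted p 6.53e-12, estimated p 0.751) were higher, and testis somatic genes (adjusted p 0.000149, estimated p 0.45) and pancreas enzymes (adjusted p 0.000129, estimated p 0.763) lower. The interaction terms were 8.83 for vtg1, 7.92 for zp3b and -4.36 for amh on the log2 scale, each at adjusted p 0.251, and -2.18 for gsdf (0.275). When adjusted over the list alone, 25 oocyte genes and 7 vitellogenins rose and 4 testis somatic genes and 4 pancreas enzymes fell. The count was 234 without EM+E2 replicate 1, when vtg1 and zp3b passed (9.36 and 8.89; zp3b was at 3.23 without replicate 2), and 1 without DMSO replicate 2 or EM replicate 1.

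At 32 d, EM against DMSO (n = 3 and 3) already showed low egg genes: 10 of 16 oocyte genes fell (median -6.06, or -5.76 with the 2 members lacking reads at their bound), and the list passed with the preset correlation (adjusted p 1.48e-56) and with an estimated one (adjusted p 0.045). The egg envelope gene zp3b fell from 37.0 ± 20.5 to 0.766 ± 0.426 CPM (log2 fold change -5.48, SE 0.61, adjusted p 0.0154) and the histone gene h1m from 49.3 ± 38.0 to 0.287 ± 0.200 CPM (log2 fold change -7.46, SE 0.91, adjusted p 0.0154). The envelope gene zp2.2 had no read in EM, at least 239-fold lower (adjusted p 0.0176). The gene zp3a.1 had 2 reads against 882 in DMSO (ratio 0.00245, 95% counting interval 0.000296 to 0.00886, adjusted p 0.0154), and the retinol saturase-like gene retsatl 3 against 1463 (ratio 0.00221, 95% counting interval 0.000456 to 0.00648, adjusted p 0.0259). Germ cell genes were lower by list test (median -1.59, adjusted p 3.2e-08, estimated p 0.562), with DDX4 at 5.20 ± 2.25 against 16.9 ± 10.9 CPM (adjusted p 0.658). Vitellogenins were lower (median -7.61, or -6.50 at bounds, adjusted p 0.00295, estimated p 0.857), with vtg1 at 0.345 ± 0.598 against 93.5 ± 162 CPM (adjusted p 0.658) and F13A1 at 0.373 ± 0.135 against 25.0 ± 42.9 CPM (0.658). Pancreas enzymes (adjusted p 8.88e-05, estimated p 0.857) were higher, and ribosomal protein (adjusted p 6.37e-07, estimated p 0.857) and fast muscle genes (adjusted p 6.36e-05, estimated p 0.857) lower. Values of amh were 7.30 ± 2.3 against 1.21 ± 1.23 CPM (adjusted p 0.658), and gsdf (0.75), FOXL2 (0.63), ESR1 (-2.15) and cyp11c1 (-1.43) did not pass.

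Of 21242 genes tested at 32 d, 46 fell and 0 rose in EM, and DESeq2 called 163. If adjusted over the list alone, 13 oocyte genes, 7 vitellogenins, 2 germ cell genes and 1 pancreas enzyme fell. Without any of the 3 EM libraries the count was 0 and zp3b, h1m, zp2.2, zp3a.1 and retsatl no longer passed, at log2 -6.11 to -5.28, -8.06 to -7.09, -11.05 to -10.95, -11.04 to -7.34 and -9.4 to -7.9, and it was 4, 96 and 19 without DMSO replicates 1, 2 and 3. Without DMSO replicate 1 zp2.2, zp3a.1 and retsatl did not pass (log2 fold changes -10.12, -7.58 and -7.35), and without DMSO replicate 3 retsatl did not (-8.35). The ribosomal protein and fast muscle lists turned, at adjusted p 0.955 and 0.736, without DMSO replicate 2, the library with most mitochondrial reads (20.4 percent) and fewest genes with a read, as did the vitellogenins without DMSO replicate 1 (0.947).

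In EM+E2 against DMSO at 32 d (n = 3 and 3), 10 of 16 oocyte genes fell (median -6.42, or -6.19 at bounds), with the list at adjusted p 2.95e-61 and, with an estimated correlation, at adjusted p 0.0428. The genes zp3b, h1m and buc, the organiser of the oocyte's germ plasm, fell from 37.0 ± 20.5 to 1.4 ± 0.593 CPM (log2 fold change -4.72, SE 0.58, adjusted p 0.0122), from 49.3 ± 38.0 to 0.269 ± 0.240 CPM (log2 fold change -7.47, adjusted p 0.0118) and from 26.3 ± 20.1 to 0.277 ± 0.245 CPM (log2 fold change -6.55, adjusted p 0.0207). The envelope gene zp3e fell from 46.5 ± 39.4 to 0.252 ± 0.183 CPM, and the claudin gene cldnd had 2 reads against 407 (ratio 0.00406, 95% counting interval 0.000490 to 0.0148, adjusted p 0.0225). Both copies of the bile acid enzyme gene CYP8B1 rose, ENSDARG00000097556 from 1.5 ± 0.942 to 24.4 ± 14.2 CPM (log2 fold change 4.12, adjusted p 0.0437) and ENSDARG00000097559 from 1.14 ± 0.809 to 34.9 ± 14.9 CPM (log2 fold change 4.79, adjusted p 0.0363), and reads may be shared between them. Germ cell genes were lower as a list (adjusted p 9.8e-20, estimated p 0.2), with DDX4 at 1.76 ± 1.03 against 16.9 ± 10.9 CPM (adjusted p 0.18, and past the test with DESeq2, all ages in 1 fit and without DMSO replicate 2, at log2 -3.64). Pancreas enzymes (adjusted p 5.42e-07, estimated p 0.857) and liver genes (adjusted p 0.000322, estimated p 0.857) were higher. The vitellogenins did not pass and their signs differ, with a median of -0.49, a mean of -0.82 and a test on the higher side (adjusted p 0.209), but passed without DMSO replicate 1 (3.65e-09) or EM+E2 replicate 2 (0.0453). The level of vtg1 was 92.1 ± 83.5 against 93.5 ± 162 CPM (log2 fold change -0.03, adjusted p 1), and amh (0.20), gsdf (-1.61) and ESR1 (-1.66) did not pass. In all 2 genes rose and 51 fell, and DESeq2 called 174. With p adjusted over the list alone, 15 oocyte and 10 germ cell genes fell. The count was 0 without any of the EM+E2 libraries, so each gene named as changed lost its call (zp3b at log2 -4.91 to -4.39, h1m at -8.16 to -6.87, zp3e at -8.13 to -7.13), and 9, 118 and 13 without DMSO replicates 1, 2 and 3. Neither copy of CYP8B1 passed without DMSO replicate 1 or 3, nor ENSDARG00000097556 with all ages in 1 fit (4.11), nor did buc and cldnd without DMSO replicate 1 (log2 fold changes -5.73 and -7.11). Without DMSO replicate 2, which is nearest to a library of 16 d, the liver list did not pass (adjusted p 0.0713).

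E2 against DMSO at 32 d (n = 3 and 3) had 0 calls by edgeR, with the smallest adjusted p at 0.0518, for zp3b, beside 1817 genes at an unadjusted p under 0.05 and 159 calls by DESeq2. Oocyte genes were lower as a list (median -4.72, adjusted p 4.82e-38, estimated p 0.129), as were germ cell genes (adjusted p 1.64e-06, estimated p 0.705). The level of zp3b was 1.33 ± 0.418 against 37.0 ± 20.5 CPM (-4.79) and that of h1m 1.19 ± 0.674 against 49.3 ± 38.0 CPM (adjusted p 0.0867). Liver genes (median 1.09, adjusted p 7.52e-16, estimated p 0.705), pancreas enzymes (adjusted p 2.43e-06, estimated p 0.857) and vitellogenins (adjusted p 0.00594, estimated p 0.857) were higher. Short of the test were vtg1 at 631 ± 969.5 against 93.5 ± 162 CPM (adjusted p 0.655), vtg3 at 308 ± 379 against 51.0 ± 85.9 CPM (0.601), amh at 0.262 ± 0.145 against 1.21 ± 1.23 CPM (0.579), and gsdf, DDX4 and ESR1 at log2 -1.64, -1.53 and -0.85. Adjusted over the list alone, 13 oocyte genes fell and 12 liver genes rose. Without DMSO replicate 2 there were 156 calls, zp3b and h1m among them, and without DMSO replicate 1 there were 2. With DESeq2, all ages in 1 fit or either block both genes passed too, and zp3b with RLE scaling and recovered reads. The vitellogenin list did not pass without DMSO replicate 2 or 3 (adjusted p 0.149 and 0.185) or E2 replicate 1 (0.19, with vtg1 at log2 -0.37).

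In EM+E2 against EM at 32 d (n = 3 and 3) yolk genes stood out: vitellogenins were higher (median 5.48, adjusted p 3.9e-15, estimated p 0.414), with other oestrogen targets (6.97e-09 and 0.562) and liver genes (3.75e-12 and 0.818). Germ cell (adjusted p 3.25e-07, estimated p 0.657) and meiosis genes (0.000241 and 0.377) were lower. Levels of vtg1 were 92.1 ± 83.5 against 0.345 ± 0.598 CPM, of F13A1 61.6 ± 23.5 against 0.373 ± 0.135 CPM and of nots 23.5 ± 4.93 against 0.631 ± 0.50 CPM, all at adjusted p 1, with log2 fold changes of 8.28, 7.39 and 5.27. Those of amh, gsdf, DDX4 and zp3b were -2.27, -2.36, -1.57 and 0.76, at the same adjusted p. When adjusted over the list alone, 5 vitellogenins and 3 other oestrogen targets rose. Over all genes edgeR called 0, beside 615 at an unadjusted p under 0.05 and 9 by DESeq2. The interaction at 32 d had 0 calls too, beside 1613 and 191. Its oocyte genes (adjusted p 1.66e-15, estimated p 0.364) and vitellogenins (0.0362 and 0.866) were higher and its globins lower (0.00401 and 0.849). Terms were 5.55 for zp3b (adjusted p 0.317), 5.52 for vtg1 (0.73) and -0.08 for amh (0.997). The zp3b term reflects mainly its lower level in E2 alone, since EM alone already held it low. If adjusted over the list alone, 8 oocyte genes rose and 3 globins fell in the interaction. Its count was 15 without DMSO replicate 2, when zp3b passed (5.87), as it did with DESeq2, all ages in 1 fit and either block, and its vitellogenin list turned without DMSO replicate 1 (adjusted p 0.361) and did not pass without E2 replicates 2 and 3 (0.179 and 0.153), EM replicates 1 and 2 (0.129 and 0.0789) or EM+E2 replicates 1 and 3 (0.0641 and 0.0672).

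At 16 d vitellogenins were higher by list test wherever E2 was given. In EM+E2 against DMSO (n = 3 and 3) vitellogenins (median 2.19, adjusted p 1.22e-09, estimated p 0.364), other oestrogen targets (median 1.69, adjusted p 1.51e-05, estimated p 0.414) and liver genes (adjusted p 8.08e-05, estimated p 0.857) were higher and brain genes lower (adjusted p 1.37e-05, estimated p 0.857). Levels of vtg3 were 15.6 ± 3.21 against 0.341 ± 0.385 CPM and of nots 8.61 ± 12.4 against 0.206 ± 0.0908 CPM. That of vtg1 was 8.15 ± 1.32 against 2.44 ± 4.23 CPM, and F13A1, with no read in DMSO, was at 21.4 ± 9.23 CPM, at least 181-fold more. Each had an adjusted p of 0.901, and DDX4 and zp3b were at log2 -0.81 and -0.06. Against EM, vitellogenins (median 4.99, or 4.78 at bounds, adjusted p 3.78e-17, estimated p 0.2), other oestrogen targets (adjusted p 4e-05, estimated p 0.45), unfolded protein response (adjusted p 3.51e-10, estimated p 0.705) and innate immune genes (adjusted p 1.36e-07, estimated p 0.857) were higher. The log2 fold changes were 5.73 for vtg3, 5.32 for F13A1 and 6.34 for RSAD2, all at adjusted p 0.863. E2 alone gave higher vitellogenins (median 1.74, adjusted p 0.000149, estimated p 0.804) and cell cycle genes (adjusted p 2.64e-06, estimated p 0.857). There vtg3 was at 7.68 ± 7.39 against 0.341 ± 0.385 CPM and vtg1, zp3b and DDX4 at log2 0.59, 0.60 and -1.09. Under EM alone, innate immune (adjusted p 6.37e-07, estimated p 0.857) and unfolded protein response genes (adjusted p 1.85e-05, estimated p 0.857) were lower and vitellogenins not past the test (0.0997). The genes vtg1, DDX4 and zp3b were at log2 -2.92, 0.43 and -0.28. In the interaction, unfolded protein response genes (adjusted p 6.55e-08, estimated p 0.804) and vitellogenins (adjusted p 0.000175, estimated p 0.807) were higher, with vtg1 at 4.07.

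With p adjusted over the list alone at 16 d, the genes higher were 2 vitellogenins and 2 other oestrogen targets in EM+E2, 5, 2 and 4 innate immune genes against EM, and 2 vitellogenins in E2. In EM, 2 innate immune genes were lower. Of 20720 genes edgeR called 0 in all 5 comparisons. Unadjusted p under 0.05 held for 389 genes in EM+E2 against DMSO, 481 against EM, 418 in E2, 398 in EM and 482 in the interaction. DESeq2 called 6, 149, 2, 107 and 34, with F13A1 and vtg3 among the first 2 sets. Without EM replicate 2 the counts were 144 against EM, 123 in EM and 10 in the interaction. E2 replicate 1 was nearest to a library of 2 d (rho 0.982), and EM replicates 1 and 3 to libraries of 8 and 32 d (0.914 and 0.925). Without these 3 libraries innate immune and unfolded protein response genes in EM did not pass (adjusted p 0.0512 and 0.112), nor the latter in the interaction (0.123). Innate immune genes in EM did not without EM replicate 1 (0.0537) or DMSO replicate 3 (0.178) alone, while vitellogenins passed there without DMSO replicate 1 (0.00366) or 3 (0.0131), and in the interaction did not without DMSO replicate 2 (0.129). The vitellogenins in E2 did not without E2 replicate 3 (0.307) or DMSO replicate 3 (0.0948), nor other oestrogen targets against EM without EM replicate 2 (0.0742) or 3 (0.074).

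At 8 d, EM+E2 against DMSO (n = 3 and 3) had higher cell cycle genes (median 1.25, adjusted p 1.84e-15, estimated p 0.562) and lower innate immune (adjusted p 1.26e-09, estimated p 0.705) and glucocorticoid-responsive genes (adjusted p 7.16e-08, estimated p 0.2). The stress genes FKBP5 and KLF9 were at 47.1 ± 11.4 against 187 ± 77.1 CPM (adjusted p 0.353) and 47.4 ± 23.3 against 152 ± 12.2 CPM (0.529). The matrix protease gene MMP9 was at 5.08 ± 1.74 against 38.5 ± 40.5 CPM (0.529) and mki67 at 49.0 ± 27.4 against 16.6 ± 3.19 CPM (0.529). F13A1 was at 3.89 ± 2.52 CPM against 2 reads (ratio 53.7, 95% counting interval 14.5 to 449, adjusted p 0.331). DDX4 and zp3b were at log2 -0.72 and 0.71. Against EM, cell cycle genes were higher (adjusted p 3.25e-07, estimated p 0.857) and glucocorticoid-responsive genes lower (adjusted p 1.19e-05, estimated p 0.275). FKBP5 was at log2 -1.75 (adjusted p 0.329) and past the test without EM replicate 1 (-1.99). EM alone had higher ribosomal protein (adjusted p 7.64e-09, estimated p 0.857) and lens and retina genes (adjusted p 3.08e-06, estimated p 0.83) and lower innate immune genes (adjusted p 0.00144, estimated p 0.857, but 0.775 without EM replicate 1). The cytokine gene il1b was at 1.39 ± 0.572 against 8.59 ± 4.73 CPM (adjusted p 0.816) and DDX4 and zp3b at log2 0.47 and 0.91. E2 alone had higher ribosomal protein genes (adjusted p 1.52e-12, estimated p 0.857) and lower cartilage and bone genes (adjusted p 7.95e-08, estimated p 0.625). F13A1 was at 1.43 ± 0.240 CPM against 2 reads (ratio 19.7, 95% counting interval 5.10 to 169, adjusted p 1) and DDX4 and zp3b at log2 -0.51 and 0.55. In the interaction cartilage and bone genes were higher (adjusted p 9.13e-05, estimated p 0.849) and ribosomal protein genes lower (adjusted p 3.47e-12, estimated p 0.857), with the cartilage collagen gene COL2A1 at 1.94 (adjusted p 0.487), and past the test without EM replicate 1 (2.14).

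Adjusted over the list alone at 8 d, 14 cell cycle genes rose and 9 innate immune and 4 glucocorticoid-responsive genes fell in EM+E2 against DMSO. So did 2 glucocorticoid-responsive genes against EM, and 4 cartilage and bone genes rose and 18 ribosomal protein genes fell in the interaction. Of 20268 genes edgeR called 1 lower in EM+E2, zgc:174862, which lies outside the naming rule and was chosen after its values were seen, with 2 reads against 4.86 ± 1.03 CPM in DMSO (ratio 0.0153, 95% counting interval 0.00183 to 0.0562, adjusted p 0.0488). It was also the 1 call against EM, at 4.89 ± 2.05 CPM (ratio 0.0148, interval 0.00178 to 0.0546, adjusted p 0.0478). Against DMSO the call ended with RLE scaling, all ages in 1 fit, the blocks (1 fit here) and without any of the 6 libraries. Against EM it ended with the same settings and without any library but EM replicate 1, without which 2254 genes passed. Without EM+E2 replicate 3 other calls were 4 against DMSO and 2 against EM. In EM edgeR called 0 (1190 at an unadjusted p under 0.05, 16 by DESeq2, and 784 without EM replicate 1) and in E2 0 (452, 1, and 1 without E2 replicate 3). In the interaction it called 0 (1975, 23, 1981 without EM replicate 1, and 1 without E2 or EM+E2 replicate 3). DESeq2 called 45 in EM+E2 against DMSO, with FKBP5, KLF9, MMP9 and mki67, and 72 against EM. EM+E2 replicate 3 had apobb.1 at 105.3 unscaled CPM, against 3699.5 and 3128 in its group, and the lists named for EM+E2 passed without it.

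At 2 d, in EM+E2 (n = 2) against DMSO (n = 2), the gene pdap1a (ENSDARG00000092546) fell from 115 ± 20.4 to 0.487 ± 0.127 CPM (log2 fold change -7.83, SE 0.62, adjusted p 0.00553). With the reads recovered from the normalized table the log2 fold change was -0.62 and did not pass. A further call, si:ch211-209l18.4, had no read in EM+E2 and was at least 101-fold lower (adjusted p 0.0424). It lies outside the naming rule and was chosen after its values were seen. Liver (adjusted p 4.84e-05, estimated p 0.857) and fast muscle genes (adjusted p 0.00171, estimated p 0.857) were higher and ribosomal protein genes lower (adjusted p 0.00731, estimated p 0.925). The gene vtg1 was at 6.89 ± 1.32 against 3.28 ± 3.43 CPM (adjusted p 0.998), with DDX4, zp3b and cyp11c1 at log2 0.18, -1.64 and -2.66. Against EM (n = 3) the log2 fold change of pdap1a was -8.05 (adjusted p 0.00515). The monocarboxylate transporter gene SLC16A6 and si:ch211-209l18.4, without reads in EM+E2, were at least 90.8-fold and 153-fold lower (0.0318 and 0.0253). Liver genes (adjusted p 7.81e-08, estimated p 0.857) and vitellogenins (median 5.88, or 4.33 at bounds, adjusted p 0.000377, estimated p 0.705) were higher, and ribosomal protein genes lower (adjusted p 6.98e-06, estimated p 0.857). Here vtg1 stood against 1 read in EM (ratio 161, 95% counting interval 28.4 to 6397, adjusted p 0.824). In the interaction pdap1a had a term of -8.18 (adjusted p 0.0169), and si:ch211-209l18.4, without reads in EM+E2, passed too (0.0335). Fast muscle genes (adjusted p 1.79e-10, estimated p 0.807) and vitellogenins (adjusted p 0.000177, estimated p 0.562) were higher there and lens and retina genes lower (adjusted p 1.23e-05, estimated p 0.857).

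Under the single treatments at 2 d edgeR called no gene. In EM (n = 3) vitellogenins (median -4.52, or -2.97 at bounds, adjusted p 2.76e-08, estimated p 0.355), other oestrogen targets (adjusted p 0.00696, estimated p 0.562) and pancreas enzymes (adjusted p 1.33e-08, estimated p 0.849) were lower. There was 1 read of vtg1 against 3.28 ± 3.43 CPM (ratio 0.0150, 95% counting interval 0.000372 to 0.0872, adjusted p 1) and DDX4, zp3b and cyp11c1 were at log2 -0.63, -0.60 and -0.45. In E2 (n = 3) lens and retina genes (adjusted p 6.37e-07, estimated p 0.857) were higher and fast muscle genes lower (adjusted p 3.99e-10, estimated p 0.83). The nitric oxide synthase gene NOS2 was at 3.42 ± 0.490 against 15.5 ± 3.68 CPM, DDX4 at 0.472 ± 0.198 against 2.23 ± 1.03 CPM, and vtg1, zp3b and cyp11c1 at log2 -1.0, 0.08 and -0.02, each at adjusted p 1. When adjusted over the list alone, 2 vitellogenins rose against EM and 2 in the interaction, where 1 fast muscle gene rose, and 1 vitellogenin fell in EM. Of 19723 genes edgeR called 0 in EM (162 at an unadjusted p under 0.05, 1 by DESeq2) and 0 in E2 (411 and 10). It called 3 lower in EM+E2 against DMSO (DESeq2 17), 4 lower against EM (DESeq2 61) and 3 lower in the interaction (DESeq2 47).

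Leaving out libraries at 2 d ended the calls. Without either EM+E2 library no gene passed against DMSO, against EM or in the interaction, and si:ch211-209l18.4 did not pass against DMSO without DMSO replicate 1, when 2 genes did. Against EM there were 2, 2 and 3 calls without EM replicates 1, 2 and 3, the losses being SLC16A6 and si:ch211-209l18.4 without replicate 1 or 2 and si:ch211-209l18.4 without replicate 3. In the interaction there were 0 without either DMSO library or without EM replicate 2, 2, 2 and 1 without E2 replicates 1, 2 and 3, and 1 and 2 without EM replicates 1 and 3. The call of pdap1a ended without DMSO replicates 1 and 2 and EM replicate 2 (log2 -8.28, -7.99 and -8.32), and that of si:ch211-209l18.4 without any library, with all ages in 1 fit and with the replicate block. With the copied column kept no call held, and SLC16A6 did not pass with the replicate block, nor pdap1a with all ages in 1 fit, against DMSO and in the interaction (-7.82 and -8.13). Libraries at 2 d are of 2 kinds. The liver gene apobb.1 is at 48.3 to 134.3 or 5822 to 7436 unscaled CPM, and myhz2 at 288.7 to 825.6 or 2655 to 4126. Both EM+E2 libraries are of the second kind, but only 1 each in DMSO, EM and E2. Without DMSO replicate 1 liver and fast muscle genes in EM+E2 against DMSO did not pass (adjusted p 0.383 and 0.455). Without E2 replicate 1 the lens and retina list in E2 turned (adjusted p 0.774), and in the interaction it did not pass (0.267). Other oestrogen targets in EM did not without DMSO replicate 1 or EM replicate 1 or 3 (0.521, 0.0507 and 0.0905). Turned too was the ribosomal protein list in EM+E2 against DMSO without DMSO replicate 1 (0.0542).

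The effect of each compound with and without the other was compared across genes, in 10 correlations between comparisons that share no library. For E2 without against with EM, Pearson's r (Spearman's rho) was -0.148 (-0.186) at 2 d, -0.288 (-0.341) at 8 d, -0.00 (0.045) at 16 d, -0.613 (-0.269) at 32 d and -0.045 (-0.017) at 64 d. For EM without against with E2 it was -0.179 (-0.288), -0.093 (-0.124), 0.162 (0.326), -0.328 (0.160) and 0.628 (0.576). The spread from leaving out libraries (jackknife SE) was 0.495, 0.170, 0.283, 0.528 and 0.258 for E2 and 0.529, 0.322, 0.416, 0.525 and 0.224 for EM, so only the EM effect at 64 d lay more than 2 such errors above 0. Genes are not independent replicates, so no p-value is given. At 32 d the EM correlation became 0.197 without E2 replicate 1, and at 2 d it became 0.221, and that of E2 0.255, without DMSO replicate 2, among other changes of sign.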

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

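The tests of explanations, other splits and genes only in the normalized table and the library-number block were chosen only after the results were seen. The response to EM against DMSO differed between 64 and 32 d in 1186 genes, 323 higher and 863 lower at 64 d, by a test of the difference itself in 1 fit of all ages (smallest adjusted p 2.53e-06), with 4 of 27 oocyte genes among the lower. For EM+E2 385 genes differed, 114 higher and 271 lower (smallest adjusted p 0.000219), and for E2 2 genes, both higher (0.0283). Of 23945 genes, edgeR called 0 in the other 9 differences between successive ages, beside 248 to 1390 at an unadjusted p under 0.05, and DESeq2 was not run on them. At 2 d the effect of E2 differed with EM in 3 genes. No group has 4 or more samples, so single outlying samples were not tested for.

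Genes found in the normalized table only, none with a symbol, were tested from recovered reads. At 64 d 235 of 733 changed in EM, 141 higher and 94 lower, 219 in EM+E2, 126 and 93, and 8 in E2, all higher. At 32 d of 740 genes 2 were lower in EM and 2 in EM+E2, and at 8 d of 700 genes 1 was lower in EM+E2 against DMSO and 1 against EM.

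The genes pdap1a, csnk1e and PHF5A had almost no raw reads in 5 of 13 EM+E2 libraries (2 d replicates 1 and 3, 8 d replicate 2, 16 d and 32 d replicates 1), the source of the call of pdap1a at 2 d. Of 10829 genes measured 6 were lost there, pdap1a standing at 0.005 of the level of other libraries of the age. Against an effect of EM+E2, pdap1a was not low in 8 of 13 EM+E2 libraries, and recovered reads of pdap1a, csnk1e and PHF5A were present, the lowest ratio being 0.64, so the loss of these 3 genes may lie in the making of the raw table. SLC16A6 is not explained so, with a recovered ratio of 0.0 as well. For CSDC2, at 0.293 on few reads, a loss in the raw table and a lower level cannot be told apart, and a change of the genome in some fish stays open for SLC16A6.

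The fall of the oocyte genes in EM at 64 d was weighed next. Scaling argues against itself as the cause, since with RLE their median lay at -9.66 relative to all genes, on a spread between genes of 2.87 (SD). A batch along the library numbers cannot be told apart from treatment, because the numbers run by treatment. The block, with 26 of 27 still lower, parts libraries only within treatments. The highest oocyte sum in EM, 99.1 CPM, lies under DMSO at 16 d (106 to 172.7), where the list member RBPMS2 led the sum. It is far under the lowest DMSO library at 64 d (5807), as pools with little or no ovary with growing oocytes would give. Whether these pools held fewer females or females with later ovaries stays open, since the labels give no sex.

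In 5 libraries the nearest library by rank correlation was of another age. For E2 2 d replicate 1 and E2 16 d replicate 1 chi-square per degree of freedom was 3.7, below the 8.0 of the closest libraries of any 1 group, so a single pool under both labels may be the source. A swap of DMSO 32 d replicate 2 with DMSO 16 d replicate 3 was argued against by the latter's nearest library, at a rho of 0.951, being EM 16 d replicate 2, of its own age. A true difference in stage between pools stays open and was not tested.

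With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real count of changed genes and the highest of the other splits were 0 and 0 for EM, 0 and 0 for E2, 1 and 0 for EM+E2 and 1 and 1118 for EM+E2 against EM at 8 d, where 5 splits reached the real count. In the same order they were 0 and 0, 0 and 3840, 0 and 0, and 0 and 0 at 16 d, and 46 and 0, 0 and 6, 53 and 0, and 0 and 0 at 32 d. In DMSO they were 1023 and 0 from 8 to 16 d, 442 and 3739 from 16 to 32 d and 4697 and 5 from 32 to 64 d. For the interactions at 8, 16 and 32 d the real count of 0 is reached by all 40 splits drawn for each, so the splits decide nothing (highest others 1, 0 and 0). The splits with 1118 (EM replicate 1 with EM+E2 replicates 1 and 3), 3840 (DMSO replicates 1 and 2 with E2 replicate 1) and 3739 (DMSO 16 d replicates 1 and 2 with DMSO 32 d replicate 2) point to a structure of the samples that the groups do not hold.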

How the results depend on the processing

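The library-number block, recovered reads, kept copied column and fit without 5 libraries were chosen only after the results were seen. Of 2504 values of named genes under an alternative, 2254 stayed on their side of the threshold (72 with the other sign, past it in neither fit), 163 no longer passed, 87 newly passed and 0 that passed in either fit turned. Of 1387 for lists 1051 stayed (24 with the other sign), 304 no longer passed, 22 newly passed and 10 turned, and of 414 counts of changed genes 268 stayed within 1.5 times. No count of genes moved beyond that for EM against DMSO at 64 d except with all ages in 1 fit and on leaving out a library. Where a result changed, the cause was not tested, unless fewer libraries or genes explain it by construction.

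With DESeq2 the counts were 2034 for DMSO at 16 against 8 d and 1007 at 32 against 16 d. For EM against DMSO they were 1, 16, 107 and 163 at 2, 8, 16 and 32 d, for E2 10, 1, 2, 159 and 2437 at 2, 8, 16, 32 and 64 d, and for EM+E2 17, 45, 6 and 174 at 2, 8, 16 and 32 d. For EM+E2 against EM they were 61, 72, 149, 9 and 158 and for the interaction 47, 23, 34, 191 and 365 at the 5 ages. With RLE scaling E2 at 32 d had 1, and EM+E2 at 8 d had 0 against DMSO and 0 against EM. With no filter on counts E2 had 13 at 32 d and 6 at 64 d, and EM 77 and EM+E2 82 at 32 d.

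With all ages in 1 fit E2 had 73, 90 and 25 at 2, 32 and 64 d, EM 116 and 4097 at 32 and 64 d, and EM+E2 against DMSO 1, 0, 129 and 3765 at 2, 8, 32 and 64 d. EM+E2 against EM had 21, 0 and 99 at 2, 8 and 64 d, and the interaction 7, 152 and 103 at 2, 32 and 64 d. With recovered reads E2 had 3 and 415 at 32 and 64 d, EM+E2 2 at 8 d, EM+E2 against EM 2 at 2 d and 2 at 8 d, and the interaction 0 at 2 d. With the copied column kept, EM+E2 at 2 d had 0 against DMSO, against EM and in the interaction.

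With the library-number block E2 had 13 at 32 d and 0 at 64 d, EM+E2 at 8 d 0 against DMSO and 0 against EM, and the interaction 1 at 32 d. Same-numbered libraries had deviations correlated above 0.1 in 5 of 12 pairs at 2 d, 4 of 18 at 8 d, 14 of 18 at 16 d, 5 of 18 at 32 d, 0 of 12 at 64 d and 11 of 26 between ages in DMSO (in every pair only for EM with EM+E2 at 16 d among the comparisons tested). As a replicate block the numbers changed no call of EM+E2 against EM at 16 d. At 8 and 32 d both blocks are 1 fit, with the counts above. At 64 d the replicate block gave 1211 for E2 and 1 for EM+E2 against EM. The ribosomal protein list in EM+E2 at 2 d turned (adjusted p 0.934). Other oestrogen targets in EM and the liver list in EM+E2 at 2 d and vitellogenins in the interaction at 32 d no longer passed, and in EM+E2 at 32 d they did. Of the other counts none moved beyond 1.5 times with this block.

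Without the 5 libraries nearest to another age E2, EM and EM+E2 had 156, 96 and 118 at 32 d, EM+E2 against EM 2 at 2 d, and the interaction 15 at 32 d. In EM at 32 d the ribosomal protein and fast muscle lists turned (0.948 and 0.748), as did the lens and retina list in E2 at 2 d (0.772).

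Of 745 list tests 244 passed, against 2 with an estimated correlation, 6 by directional and 35 by mixed fry. The correlation of the E2 effects at 8 d was -0.46 over genes at a mean of 10 CPM or more, and that of the EM effects at 32 d was 0.15 from log2 CPM means with a prior count of 5, the opposite sign.

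Leaving out 1 library, the lowest and highest counts in DMSO were 2358 and 4848 at 8 against 2 d, 260 and 702 at 16 against 8 d, 177 and 662 at 32 against 16 d and 2171 and 4071 at 64 against 32 d. For EM they were 0 and 784, 0 and 123, 0 and 96, and 2031 and 7891 at 8, 16, 32 and 64 d. For E2 they were 0 and 1, 0 and 156, and 0 and 2493 at 8, 32 and 64 d. For EM+E2 they were 0 and 3, 0 and 4, 0 and 118, and 812 and 7569 at 2, 8, 32 and 64 d. Against EM they were 0 and 3, 0 and 2254, 0 and 144, and 0 and 177 at 2, 8, 16 and 64 d, and in the interaction 0 and 2, 0 and 1981, 0 and 10, 0 and 15, and 0 and 234 at the 5 ages. The list calls ranged from 232 to 255. The correlation of E2 effects ranged from -0.39 to 0.26 at 2 d and from -0.62 to -0.01 at 32 d, and that of EM effects from -0.39 to 0.22 and from -0.46 to 0.20, with the sign opposite to the full data without DMSO 2 d replicate 2 at 2 d (0.26 and 0.22) and, for EM, without E2 32 d replicate 1 (0.20). At 2 d it turned too without EM replicate 2 for EM (0.066) and without E2 replicate 1 for E2 (0.033), and at 64 d for E2 without EM+E2 replicate 2 (0.20). Further values changed sign for EM at 8 and 16 d and for E2 at 16 and 64 d. The adjusted p of 6 lists that turned ranged as follows. In EM at 32 d it went from 4.57e-10 to 0.955 (without DMSO replicate 2, turned) for ribosomal protein genes, from 4.47e-08 to 0.736 (the same library) for fast muscle genes and from 5.33e-06 to 0.947 (without DMSO replicate 1, turned) for vitellogenins. In the interaction at 32 d it went from 0.000226 to 0.361 for vitellogenins, turned without DMSO replicate 1. At 2 d it went from 3.18e-06 to 0.0542 for ribosomal protein genes in EM+E2, turned without DMSO replicate 1, and from 3.51e-12 to 0.774 for lens and retina genes in E2, turned without E2 replicate 1.

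Depth limits genes with few reads, since the smallest library held 4039030.0 reads. The fit of all treatments in 1 model left the 4 DMSO counts within 1.5 times.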

Other observations

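Sums over lists, in unscaled CPM, follow, with RBPMS2 leading the oocyte sum at 16 d. In DMSO the 27 oocyte genes summed to 144.4 CPM at 16 d, 467.6 ± 276.1 at 32 d and 9975 ± 4324 at 64 d (SD), while E2 alone stood at 103.8 ± 15.29 at 32 d and 4660 ± 48.91 at 64 d, and EM+E2 at 64 d held 128.4 and 1691 in its 2 libraries. Vitellogenins at 64 d summed to 5835 ± 7726 CPM in DMSO, with libraries from 453.1 to 14688, to 3208 ± 96.26 in E2, 1824 ± 958.6 in EM+E2 and 10.5 ± 1.79 in EM.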
